A study of Mus musculus with 2 samples.

How the data were processed

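Dendritic cells were grown with GM-CSF from lineage-negative CX3CR1+ c-kit+ bone marrow cells of C57BL/6 mice with 1 Cx3cr1 allele replaced by GFP. Per the labels' protocols, total RNA was extracted with the RNeasy mini kit and amplified and labelled with Agilent's linear amplification kit for low RNA input. Each of 2 Whole Mouse Genome arrays compared CD11c+CD103+ with CD11c+CD103- cells of 1 independent biological replicate, with CD103- cells in the red channel (Cy5) on array 1 and CD103+ cells in red on array 2. These directions come from the source names and descriptions, since the characteristics of array 2 give CD103- for both channels. The turned ratio of Itgae, 3.51 and 3.49 on arrays 1 and 2, bears on the direction of each array.

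Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.1.3.1. The deposited scanner files hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in both channels, without normalization. They also hold processed signals in intensity units, which the authors' software had background-subtracted, detrended and dye-normalized by linear scaling and lowess. Per the file headers, the deposited log ratio is the log10 of processed red over processed green. The deposited series values equal that log10 ratio to within 0.00493 on array 1 and 0.00498 on array 2. The ratio is exactly 0 for 21.4% and 30.1% of gene spots. Each file holds 45018 spots, 43379 of them for genes, which carry 41174 probes, 245 of them with 10 spots and 40929 with 1. The median mean signal was 310.2 in red and 178 in green on array 1, over backgrounds of 57.5 and 48, and 210.6 and 225 on array 2, over 53 and 45.5. No spot was saturated, and the scanner software marked 8 spots on array 1 and 16 on array 2 as outliers.

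Mean signals were corrected with the median local background by normexp with an offset of 50 and normalized by loess within each array, with control and outlier spots left out of the loess curve. Analyses used limma 3.58.1 in R 4.3.3 with the package data.table (version 1.17.8). Log2 ratios were turned to CD103+ over CD103- cells and the spots of a probe averaged. A probe was tested when it was well above background, by the scanner software's criterion in at least 0.5 of its spots, for the same population on both arrays, which left 22132 probes. Differences were tested, two-sided, with limma's moderated test on 1 coefficient, the mean turned ratio, with 1 residual degree of freedom, a variance prior that follows intensity (8.39 prior degrees of freedom) and Benjamini-Hochberg adjustment over all probes tested. A difference was called at an adjusted p under 0.05. With the dyes exchanged, probe-specific dye effects cancel in the mean and add to the spread. No paired analysis was possible beyond this, because each array is itself a direct ratio and the design has a single group of 2 arrays. Where a population was not well above background for a probe on either array, its fold is given as a lower bound on the mean of the arrays. The bound sets that population, on each array, at its measured level or at the lowest level called well above background for it on that array, whichever is higher.

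A gene was represented by its brightest tested probe. Probe names were brought to current symbols through the accessions of a RefSeq table, which matched 22951 probes (55.7%), and otherwise kept as deposited; no coordinates were used. Of 15223 tested names, 11412 had a gene symbol. In 5061 genes several probes were tested, and in 4 of these, Gas5, Tmem106b, C130026I21Rik and Serpinb1b, probes were called in opposite directions. Before the data were examined, the test, the alternatives, 28 gene lists and the rule for named genes were fixed. Named were the genes of the sort markers of progenitors and progeny (Itgae, Itgax, Cx3cr1 and Kit) and Itgb7, the partner chain of CD103. Also named were the 12 genes with the largest positive and the 12 with the largest negative mean ratio among called genes with a symbol and the same sign on both arrays, and up to 4 called members of each list with the largest absolute ratio, filled to 2 with uncalled members where fewer passed. Genes outside this rule are described as named after their values were seen. Lists were tested against all other genes with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. At a preset correlation its p-values rest on the spread across genes and not on that between the 2 arrays.

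Alternatives were the processed signals, the series values, no background subtraction, an offset of 0, median centring in place of loess, scaling between arrays, no filter on dim probes, a filter on all channels, outlier spots kept, other variance priors, an adjusted p under 0.1, a 2-fold minimum, each array alone, camera with an estimated correlation, fry, and the mean over a gene's probes. Scaling to the E1A spike-in probes was added after the data were seen. These are 10 control probes with 32 spots each for RNA that Agilent's protocol adds to both labelled samples in designed ratios. The designed ratios follow the dye and cancel in the mean of the turned arrays. Spike-in scaling subtracts the same fixed value from every ratio, so its p-values carry no error of that value. On simulated data with the spread of these arrays and 200 of 22132 probes changed, 5.12% of changes of 0.5 on the log2 scale, 75.2% of changes of 1 and 99.8% of changes of 2 were recovered, with 12.8% of calls false. With 5158 probes changed, the shares were 47.1%, 98.0% and 99.99%, with 5.26% false. Simulated probes were drawn independently from the fitted variance prior. The false shares therefore leave out errors that probes of an array share, and do not measure the false share of the real calls. Other control spots were left out.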

Results

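Messenger RNA levels of 2 populations of mouse dendritic cells were compared on 2-colour oligonucleotide arrays. Progenitors that carried CX3CR1 and c-kit and lacked lineage markers were sorted from the bone marrow of reporter mice with GFP in 1 Cx3cr1 allele. They were grown with GM-CSF, a growth factor that drives myeloid and dendritic cell development, and the CD11c-positive progeny was separated into cells with and without CD103, the integrin alpha E chain. The 2 arrays held independent biological replicates (n = 2), and each array set CD103+ cells against CD103- cells with the dyes exchanged between replicates. Of 41174 probes, 58.2% on array 1 and 52.8% on array 2 were well above background in CD103+ cells, and 64.1% and 53.2% in CD103- cells. The 22132 probes that were well above background in the same population on both arrays were tested, and they carried 15223 gene names. Values are log2 ratios of CD103+ over CD103- cells, given as the mean ± SD of the 2 arrays, and the number of arrays limits their precision.

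The comparison asked how the transcriptome of CD103+ dendritic cells differed from that of CD103- cells grown from the same progenitors. Itgae, which encodes CD103 itself, was 11.3-fold higher in the CD103+ population, with a log2 ratio of 3.50 ± 0.012 (SD, n = 2) and an adjusted p = 1.55e-06 by limma's moderated test. Among the genes that differed most, the mannose receptor Mrc1 was 60.4-fold higher in CD103- cells and the chitinase-like Chil3 51.8-fold higher. Of 27 maturation genes 19 were higher in CD103+ cells, whereas macrophage, neutrophil-associated, pattern recognition and lysosomal genes were mostly higher in CD103- cells. Itgb7, the beta chain that pairs with CD103, had a log2 ratio of 0.88 ± 0.37 (adjusted p = 0.0144), and the progenitor receptor Kit one of 0.96 ± 0.0093 (adjusted p = 0.00273). Itgax, which encodes the CD11c shared by both sorts, was at -0.10 ± 0.077 (adjusted p = 0.821). A second probe of Itgax had the opposite sign and was not called either (0.29 ± 0.083, adjusted p = 0.275). For Itgae a second probe gave a smaller ratio of 2.84 ± 0.047. Neither probe of Cx3cr1 was well above background in either population on either array. Itgb7 lost its call when ratios were scaled to spike-in RNA (0.42, adjusted p = 0.111), and both Itgb7 (0.64, adjusted p = 1) and Kit (0.74, adjusted p = 0.792) lost theirs with median centring in place of loess.

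In all, 5158 of the 22132 probes differed between the populations, 2404 higher and 2754 lower in CD103+ cells, so that 46.6% of them were higher. By gene, taking the brightest tested probe, 1817 were higher and 1926 lower. Large differences lay mostly on one side, since 350 called probes were at least 4-fold lower in CD103+ cells and 124 at least 4-fold higher. These counts were 577 and 282 with the scanner's processed signals, 409 and 52 with median centring in place of loess, and 594 and 41 with spike-in scaling. Without any test, 1605 probes were at least 2-fold different in the same direction on both arrays, 677 higher and 928 lower, against 1 probe with 2-fold differences in opposite directions. With median centring, 1315 were 2-fold in the same direction and 130 in opposite directions. Array 1 alone gave 2097 probes past 2-fold and array 2 alone gave 2476. Across the tested probes, which are not independent replicates, the turned ratios of the arrays had a Pearson correlation of 0.839 and a Spearman correlation of 0.679, against a median SD between arrays of 0.166. The split depended on the scaling. Median centring, under which the median SD between arrays was 0.504, ended the calls of 53 of the 123 genes followed and reversed 0. It moved the median ratio of all tested probes from -0.0092 to -0.25 and called 483 higher and 1055 lower, or 31.4% higher. Scaling to spike-in RNA, an alternative added after the data were seen, moved that median to -0.47 and called 1113 higher and 12337 lower, or 8.28% higher.

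**Figure D1:**
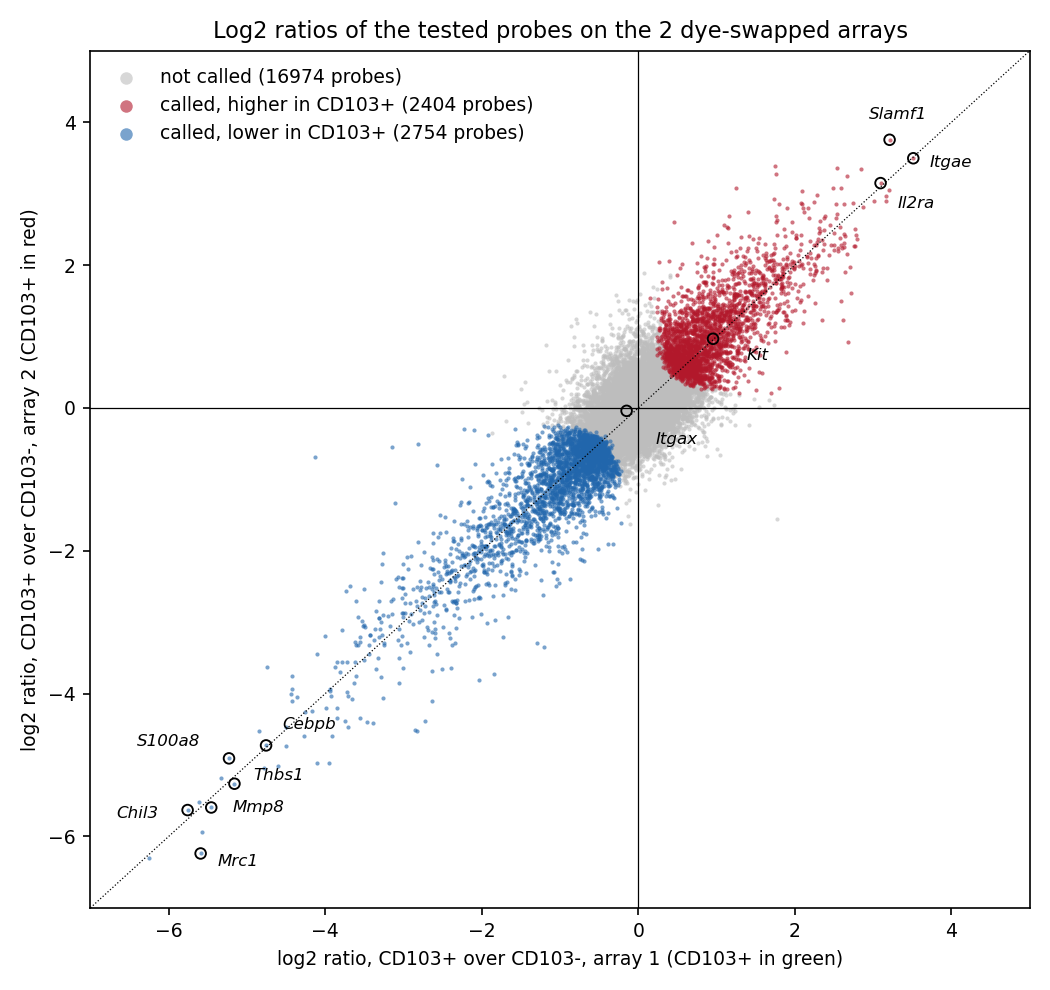
Log2 ratio of CD103+ over CD103- cells for each of the 22132 tested probes on array 1 (horizontal axis) and array 2 (vertical axis), in red for the 2404 called higher, in blue for the 2754 called lower and in grey for the rest, with 11 named genes circled and the line of equality dotted. Itgae lies at 3.51 and 3.49 on the 2 arrays and Mrc1 at -5.59 and -6.24.

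Slamf1, Dapk2 and Il2ra followed Itgae among the 12 genes with the largest positive ratios. Slamf1, a signalling lymphocyte activation receptor also called CD150, was at 3.48 ± 0.38 (adjusted p = 3e-06). Il2ra, the alpha chain of the interleukin 2 receptor, was at 3.12 ± 0.037 or 8.70-fold (adjusted p = 1.39e-06), Cd7, a surface receptor of T and NK cells, at 2.96 ± 0.086 (adjusted p = 2.15e-06), and Txk, a Tec family kinase, at 2.85 and 3.34 on arrays 1 and 2 (adjusted p = 4.22e-06). Dapk2, a calmodulin-regulated kinase, was at 3.13 ± 0.11, the succinate receptor Sucnr1 at 2.96 ± 0.41 and Fxyd4, a regulator of the sodium pump, at 3.07 ± 0.15. The cadherin Cdh17 was at 2.83 ± 0.35, and the actin-binding proteins Aif1l and Scin were at 2.81 ± 0.089 and 2.74 ± 0.16. Ptprf, a receptor tyrosine phosphatase, was at 2.64 ± 0.50 (adjusted p = 1.5e-05, the highest among these 12). Txk and Sucnr1 were well above background in CD103- cells on 1 of the 2 arrays. A second probe of Slamf1, not well above background in CD103- cells on either array, was at least 1.89-fold higher in CD103+ cells, one of Txk gave 1.59 ± 0.36, and one of 3 for Ptprf, at 0.47 ± 0.14, was not called (adjusted p = 0.0785).

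Mrc1, Chil3, F13a1 and Mmp8 led the 12 genes with the largest negative ratios. Mrc1 stood at -5.92 ± 0.46 (adjusted p = 2.05e-07) and Chil3, a secreted macrophage protein also called Ym1, at -5.69 ± 0.090 (adjusted p = 2.11e-07). Its close relative Chil4 was at -5.26 ± 0.10, and since the sequences of these paralogs are nearly identical, which of them bound each probe is uncertain. F13a1, the coagulation factor XIII A subunit, was 47.4-fold higher in CD103- cells (-5.57 ± 0.061), Mmp8, the neutrophil collagenase, 46.1-fold (-5.53 ± 0.10), and Thbs1, the matrix protein thrombospondin, 37.0-fold (-5.21 ± 0.072). S100a8, a subunit of calprotectin, was at -5.07 ± 0.23 (adjusted p = 2.11e-07). Cebpb, a transcription factor of myeloid differentiation, was 26.7-fold higher in CD103- cells (-4.74 ± 0.021). Camk2d, a calmodulin-dependent kinase, was at -4.91 ± 0.18, Perp, a desmosomal membrane protein, at -4.81 ± 0.29, and Wfdc21, a secreted WAP domain protein, at -4.69 ± 0.24. Sh3bgrl2 was not well above background in CD103+ cells on either array and was at least 17.8-fold higher in CD103- cells (adjusted p = 1.53e-06), so that its place among the 12 rests on a ratio against background. Other probes of Thbs1 (-2.59 ± 0.073 and -3.26 ± 0.077), Camk2d (-1.77 ± 0.46 and -3.45 ± 0.24) and Cebpb (-3.46 ± 0.56) were called in the same direction with smaller ratios. A further Camk2d probe, not well above background in CD103+ cells on either array, was at least 1.57-fold higher in CD103- cells.

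**Figure D2:**
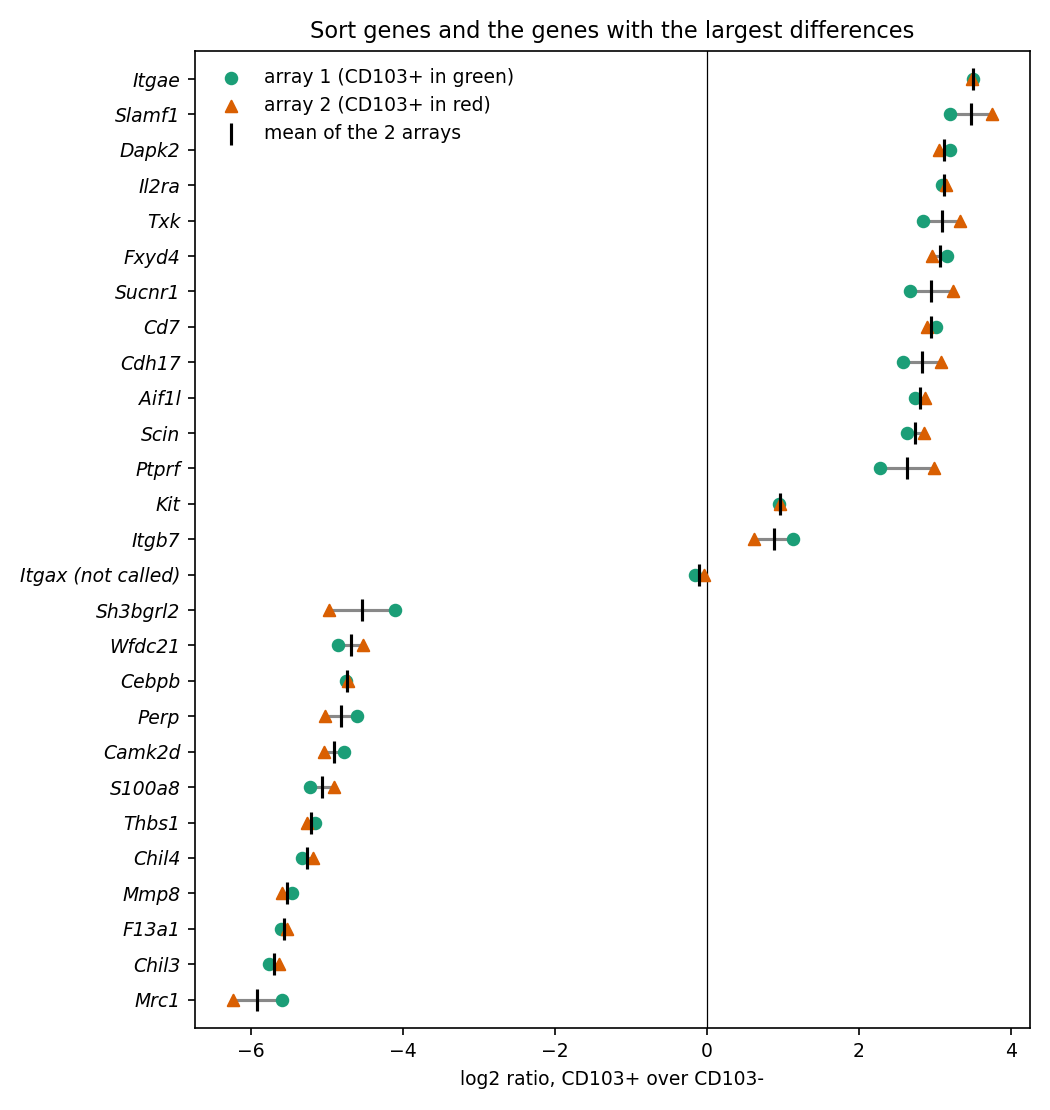
Log2 ratio of CD103+ over CD103- cells for Itgae, Itgax, Kit and Itgb7 and for the 12 genes with the largest positive and the 12 with the largest negative ratios, with Itgae in both sets, shown on array 1 (circles), on array 2 (triangles) and as their mean (black ticks). Kit marked the sorted progenitors, and Itgb7 encodes the partner chain of CD103 and was not a sort marker. Among the largest positive ratios the single-array value closest to 0 is 2.29 for Ptprf on array 1, and Sh3bgrl2 is drawn at its ratio against background.

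Markers of dendritic cell subsets differed in both directions. Of 16 tested markers of type 1 conventional dendritic cells, the cross-presenting subset, 9 were higher and 3 lower in CD103+ cells, with the same counts adjusted over the list alone and a median of 0.59. Wdfy4, which is needed for cross-presentation, was at 1.68 ± 0.33 (adjusted p = 8.16e-04) and the adhesion molecule Cadm1 at 1.30 ± 0.16 (adjusted p = 1.16e-04), above background in CD103- cells on 1 of 2 arrays. The scavenger receptor Cd36 went the other way at -2.34 ± 0.66, as did the lysosomal amidase Naaa at -1.49 ± 0.39. The 4 not called, named after their values were seen, were Xcr1 (0.27 ± 0.13), Batf3 (0.25 ± 0.030), Id2 (0.44 ± 0.64) and Tlr3 (-0.34 ± 0.29). This list ranked above the other genes by camera (adjusted p = 0.0284), but not with an estimated correlation (adjusted p = 0.772 with an estimated correlation), with median centring (adjusted p = 0.0666) or over probes above background in all channels (adjusted p = 0.126), in a range from 0.00973 to 0.772 over its alternatives. Of 15 markers of type 2 conventional dendritic cells, 6 were higher and 3 lower, again with the same counts adjusted over the list alone. Besides Cd7, the membrane protein Adam23 was higher (2.10 ± 0.44), and the transcription factors Zeb2 (-2.53 ± 0.25) and Klf4 (-2.38 ± 0.056) were lower. Named after its value was seen, the remaining lower gene was Sirpa (-1.62 ± 0.13). The 6 not called, also named afterwards, were Irf4, Itgam, Notch2, Mgl2, Clec10a and S1pr3. The median of the type 2 list was 0.32, or -0.14 with spike-in scaling (camera adjusted p = 0.36). Among 10 plasmacytoid dendritic cell markers, 5 were higher and 2 lower over all genes and over the list alone, with a median of 0.38, or -0.078 with spike-in scaling (camera adjusted p = 0.36). The nucleic acid sensor Tlr7 was 21.5-fold higher in CD103- cells (-4.43 ± 0.23), while Pacsin1 was at 1.68 ± 0.61 and the transcription factor Spib at 1.17 ± 0.32. Siglech, an inhibitory lectin, was not well above background in CD103- cells on either array and was at least 2.70-fold higher in CD103+ cells (adjusted p = 4.68e-05). Of 6 Langerhans cell genes, 4 were higher and 1 lower in CD103+ cells, with the same counts adjusted over the list alone (median 1.06, camera adjusted p = 0.144). Langerin, encoded by Cd207, was at 2.13 ± 0.31, and the adhesion molecules Epcam and Cdh1 were at 1.51 ± 0.049 and 1.18 ± 0.085, against -1.72 ± 0.14 for the lipid-presenting Cd1d1. Median centring ended the calls, with log2 ratio and adjusted p in brackets, of Wdfy4 (1.47, 1), Naaa (-1.63, 1), Adam23 (1.81, 0.404), Klf4 (-2.69, 0.095), Pacsin1 (1.38, 0.411), Spib (0.85, 0.844), Cd207 (1.82, 0.0534), Epcam (1.20, 0.629), Cdh1 (0.97, 1) and Cd1d1 (-2.01, 0.267).

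Most maturation genes and some MHC class II genes were higher in CD103+ cells. Of 27 maturation genes, 19 were higher, 0 were lower and 8 were not called, and 21 were higher when adjusted over the list alone. The activation marker Cd83 was 3.58-fold higher (1.84 ± 0.0047, adjusted p = 3.98e-05). Stat4, which transmits interleukin 12 signals, was at 1.81 ± 0.40, the actin regulator Marcks at 1.73 ± 0.82, and the co-stimulatory ligand Cd80 at 1.72 ± 0.67, with a second probe of Cd80 not called at 0.26 ± 0.10 (adjusted p = 0.304). The list median of 1.03 ranked above the other genes (camera adjusted p = 2.6e-08; adjusted p = 0.765 with an estimated correlation) and was 0.57 with spike-in scaling. Of 13 MHC class II genes, 5 were higher and 1 lower, or 8 and 1 adjusted over the list alone, with a median of 0.96, or 0.61 on array 1 and 0.92 on array 2 (camera adjusted p = 0.00213; adjusted p = 0.772 with an estimated correlation). H2-Ob and H2-Oa, the chains of the peptide-loading inhibitor, were at 1.77 ± 0.21 and 1.39 ± 0.077, the class II transactivator Ciita at 1.44 ± 0.21 and H2-Eb1 at 1.33 ± 0.30, while the protease Ctss, named after its value was seen, was the lower one at -1.10 ± 0.21. Of 21 genes of MHC class I presentation, 3 were higher and 1 lower, or 4 and 2 adjusted over the list alone, with a median of 0.13, or -0.16 with median centring and -0.33 with spike-in scaling (camera adjusted p = 0.483). The peptide transporter genes Tap1 and Tap2 were at 0.94 ± 0.075 and 0.56 ± 0.30 and the vesicle regulator Rab27a at 0.57 ± 0.29, with a second probe of Rab27a not called at 0.25 ± 0.39 (adjusted p = 0.397). Cybb, the phagocyte oxidase subunit in the same list, was 4.30-fold higher in CD103- cells (-2.10 ± 0.28). Tap2 and Rab27a lost their calls with spike-in scaling (0.10 and 0.10, adjusted p = 0.611 and 0.587), and on array 2 they stood at 0.35 and 0.36. Tap2 was not called without a filter on dim probes either (adjusted p = 0.065). Median centring ended the calls, with log2 ratio and adjusted p in brackets, of Cd83 (1.60, 0.701), Stat4 (1.52, 0.305), Marcks (1.53, 0.928), Cd80 (1.40, 0.396), H2-Ob (1.45, 0.238), Ciita (1.13, 1), H2-Oa (1.12, 1), H2-Eb1 (1.13, 1), Tap1 (0.60, 1), Tap2 (0.25, 1), Rab27a (0.24, 1) and Cybb (-2.40, 0.0576).

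Macrophage and neutrophil-associated genes were mostly lower in CD103+ cells. Each population was measured as a bulk. Expression by dendritic cells therefore cannot be told apart from a different mix of cells inside the gates, for these or the other lists. Of 24 tested monocyte and macrophage genes, 15 were lower and 2 higher in CD103+ cells, or 15 and 4 adjusted over the list alone. Besides Mrc1 and Chil3, the lysozyme Lyz1 was 18.2-fold higher in CD103- cells (-4.18 ± 0.79, adjusted p = 6.88e-06) and the scavenger receptor Marco 12.6-fold higher (-3.66 ± 0.57, adjusted p = 3.13e-06). The list median was -1.68 (camera adjusted p = 2.07e-06; adjusted p = 0.772 with an estimated correlation). Of 17 neutrophil-associated genes, 14 were lower and 2 higher, or 14 and 3 adjusted over the list alone, with a median of -1.86 (camera adjusted p = 2.6e-07; adjusted p = 0.772 with an estimated correlation). After Mmp8 and S100a8 came S100a9, the other calprotectin subunit, at -4.18 ± 0.35 and the granule peptide Camp at -2.49 ± 0.41, above background in CD103+ cells on 1 of 2 arrays. Named after their values were seen, the exceptions were the protease inhibitors Stfa2 (2.08 ± 0.26) and Stfa3 (0.46 and 2.60 on arrays 1 and 2) in the neutrophil list, and the complement genes C1qa (0.61 ± 0.20) and C1qb (0.50 ± 0.071) in the macrophage and the complement lists.

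Pattern recognition and degradative genes shared that direction. Of 26 pattern recognition genes, 18 were lower and 0 higher in CD103+ cells, or 18 and 1 adjusted over the list alone (median -1.27, camera adjusted p = 3.18e-08; adjusted p = 0.765 with an estimated correlation). After Tlr7, the C-type lectin Clec4a3 was at -4.03 ± 0.25, the lectin Clec4e, also called Mincle, at -2.61 ± 0.25, and the lipopolysaccharide receptor Tlr4 at -2.60 ± 0.49. Of 26 lysosomal genes, 17 were lower and 0 higher, or 18 and 1 adjusted over the list alone (median -1.05, camera adjusted p = 2.6e-08; adjusted p = 0.765 with an estimated correlation). The proteases Ctsk and Ctsd were 11.3-fold and 10.7-fold higher in CD103- cells (-3.50 ± 0.22 and -3.42 ± 0.13), the proton pump subunit Atp6v0d2 7.65-fold (-2.94 ± 0.095) and Psap, the precursor of saposins, 5.21-fold (-2.38 ± 0.35). A second probe of Ctsd gave -1.94 ± 0.33. Of 17 complement and Fc receptor genes, 7 were lower and 2 higher, or 8 and 4 adjusted over the list alone (median -0.26, camera adjusted p = 0.0242; adjusted p = 0.772 with an estimated correlation). Complement C3 was at -3.70 ± 0.20, with a second probe, above background in CD103+ cells on 1 of 2 arrays, at -1.54 ± 0.37. Factor B, encoded by Cfb, was at -2.45 ± 0.30, and the immunoglobulin receptors Fcgr4 and Fcgr2b were at -1.84 ± 0.27 and -1.81 ± 0.19. With median centring the calls ended, with log2 ratio and adjusted p in brackets, for Ctsd (-3.63, 0.0806), Psap (-2.52, 0.837) and Fcgr2b (-2.01, 0.715).

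Most tested chemokine genes and 8 of 17 tested cytokine genes were higher in CD103- cells. Of the genes on the arrays, 15 of 25 chemokine and 17 of 26 cytokine genes passed the filter for testing. Of the cytokine genes, 8 were lower and 1 higher in CD103+ cells, or 9 and 1 adjusted over the list alone (median -0.48, camera adjusted p = 8.24e-05; adjusted p = 0.765 with an estimated correlation). The inflammatory Il1b was at -2.93 ± 0.32 and its antagonist Il1rn at -2.84 ± 0.25, while Il1a was at -3.15 ± 0.64, above background in CD103+ cells on 1 of 2 arrays, and the macrophage growth factor Csf1 was at -2.44 ± 0.13. The exception, named after its value was seen, was the interleukin 12 subunit Il12b at 1.49 ± 0.29, above background in CD103- cells on 1 of 2 arrays. Of 15 chemokine genes, 9 were lower and 2 higher, or 9 and 3 adjusted over the list alone. Their median was -1.66, with -1.93 on array 1 and -0.50 on array 2 (camera adjusted p = 0.00867; adjusted p = 0.772 with an estimated correlation). The higher ones, named after their values were seen, were Ccl22 at 0.68 and 1.62 on arrays 1 and 2 and Cxcl16 at 0.67 ± 0.059. The myeloid chemokine Ccl6 was at -3.25 ± 0.46, platelet factor 4, encoded by Pf4, at -3.02 ± 0.69, and Ccl3, a ligand of CCR1 and CCR5, at -2.69 ± 0.44. Cxcl3, a neutrophil attractant, stood at -4.13 and -0.69 on arrays 1 and 2 (mean -2.41 ± 2.43, adjusted p = 0.0147), and robust estimation of the spread ended its call (adjusted p = 0.268). Of 21 chemokine receptor genes on the arrays, 10 were tested. Among these 10, 3 were higher and 3 lower, with the same counts adjusted over the list alone. The list median was 0.0025, or -0.0033 without background subtraction, -0.27 with median centring and -0.46 with spike-in scaling (camera adjusted p = 0.925). Ccr2, the receptor that brings monocytes out of the marrow, was 7.18-fold higher in CD103- cells (-2.84 ± 0.35). Ccr6 was at 2.02 ± 0.10, the lymph node homing receptor Ccr7 at 1.44 ± 0.42 and the follicle homing receptor Cxcr5 at 1.25 ± 0.50. With median centring the calls ended, with log2 ratio and adjusted p in brackets, for Ccl6 (-3.37, 0.506) and Ccr7 (1.14, 0.927).

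Sterol synthesis and cell cycle genes showed smaller ratios. Of 23 cholesterol genes, 13 were lower and 0 higher in CD103+ cells, or 18 and 0 adjusted over the list alone (median -0.61, camera adjusted p = 2.99e-06; adjusted p = 0.765 with an estimated correlation). The LDL receptor gene Ldlr was at -1.23 ± 0.25, the sterol synthesis enzymes Mvd and Lss were at -1.15 ± 0.61 and -0.78 ± 0.44, and Hmgcs1 was at -0.78 ± 0.016. On array 1 alone Mvd was at -0.72 and Lss at -0.46. All 4 kept their direction with larger ratios but lost their calls with median centring, with log2 ratio and adjusted p in brackets: Ldlr (-1.39, 1), Mvd (-1.41, 0.794), Lss (-1.12, 0.704) and Hmgcs1 (-0.98, 1). Of 40 proliferation genes, 4 were lower and 0 higher over all genes, while adjusted over the list alone 0 were lower and 0 higher by limma, against 9 at an unadjusted p under 0.05. The 4 were the replication clamp Pcna (-0.89 ± 0.31), the spindle protein Nusap1 (-0.56 ± 0.032) and the mitotic regulators Cdk1 (-0.48 ± 0.049, adjusted p = 0.0425) and Ccnb1 (-0.47 ± 0.016, adjusted p = 0.0475). A second probe of Nusap1 was at -0.040 ± 0.28 (adjusted p = 0.898), and one of 3 probes of Ccnb1 was not called at -0.49 ± 0.21 (adjusted p = 0.0502). With median centring all 4 ratios were larger but not called, with log2 ratio and adjusted p in brackets: Pcna (-1.13, 1), Nusap1 (-0.83, 1), Cdk1 (-0.80, 1) and Ccnb1 (-0.79, 1). Cdk1, Ccnb1 and Nusap1 also missed the threshold without a filter on dim probes (adjusted p = 0.0881, 0.0982 and 0.0526). So did Cdk1 and Ccnb1 with a variance prior without trend (0.0597 and 0.066) or a robust one (0.0512 and 0.057), and Cdk1 with the series values (0.0506). The proliferation list, with a median of -0.24 (-0.38 on array 1 and -0.14 on array 2), ranked below the other genes (camera adjusted p = 0.00533; adjusted p = 0.84 with an estimated correlation), though not with median centring (adjusted p = 0.109, in a range from 2.47e-05 to 0.84 over its alternatives). Of 22 glycolysis and hypoxia genes, 1 was lower and 0 were higher, with the same counts adjusted over the list alone (median -0.052, camera adjusted p = 0.455). That gene was the oxygen sensor Egln3 (-1.59 ± 0.27), and the mitophagy receptor Bnip3 had a ratio of -0.66 ± 0.44 (adjusted p = 0.0561), and was not called. It passed with the scanner's processed signals (-0.70, adjusted p = 0.0136), the series values (0.0165), no background subtraction (0.0475), an offset of 0 (0.0308), a variance prior without trend (0.0363) and spike-in scaling (-1.12, adjusted p = 0.0027). Of 20 stress and immediate early genes, 4 were higher and 2 lower, with the same counts adjusted over the list alone. Their median was 0.18, with -0.093 on array 1 and 0.26 on array 2, or -0.11 with median centring and -0.29 with spike-in scaling (camera adjusted p = 0.455). Heme oxygenase, encoded by Hmox1, was at -1.96 ± 0.29, and Gadd45b, Nr4a1 and Fosb, which respond early to activation, were at 1.69 ± 0.38, 1.34 ± 0.58 and 1.29 ± 0.22. The calls of Egln3 (-1.85, 0.308), Hmox1 (-2.27, 0.0856), Gadd45b (1.41, 0.527), Nr4a1 (1.02, 1) and Fosb (0.95, 0.751) ended with median centring too.

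Genes of progenitors and of other blood lineages differed in both directions. Of the genes on the arrays, 14 of 20 progenitor, 7 of 17 mast cell and basophil, 12 of 20 lymphoid and 5 of 11 erythroid and megakaryocyte genes were tested. The rest did not pass the filter for testing, which required signal well above background. Of 14 progenitor genes, 5 were higher and 4 lower in CD103+ cells, or 6 and 5 adjusted over the list alone, with a median of 0.27, or -0.19 with spike-in scaling (camera adjusted p = 0.36). Flt3, the receptor for a dendritic cell growth factor, was 5.68-fold higher in CD103+ cells (2.51 ± 0.34), Cd34 5.08-fold (2.35 ± 0.0024) and the transcription factor Gata2 4.52-fold (2.18 ± 0.020). Spink2, a protease inhibitor, was 8.61-fold higher in CD103- cells (-3.11 ± 0.12). Among 7 mast cell and basophil genes, 3 were higher and 2 lower, with the same counts adjusted over the list alone, and the median was 0.062, or -0.40 with spike-in scaling. The mast cell protease Cpa3 was at 2.34 ± 0.52, the histamine-forming enzyme Hdc at 2.22 ± 0.65 and the integrin Itga2b at 2.04 ± 0.77, against -2.12 ± 0.12 for the transcription factor Mitf, above background in CD103+ cells on 1 of 2 arrays. That list was not called (camera adjusted p = 0.64), but passed over probes above background in all channels (adjusted p = 0.0445, and 0.867 at most over its alternatives). That filter removed both lower genes, Mitf and Il4, and left a median of 2.04. Of 12 lymphoid genes, 6 were higher and 2 lower, or 7 and 2 adjusted over the list alone (median 0.51, camera adjusted p = 0.134). With the same all-channel filter this list passed too (adjusted p = 0.0459, and 0.772 at most over its alternatives). Il2rb, the beta chain of the interleukin 2 receptor, was 5.97-fold higher in CD103+ cells (2.58 ± 0.30), the T cell receptor chain Cd3g was at 1.54 ± 0.0045, and the kinase Blk at 1.33 ± 0.23, above background in CD103- cells on 1 of 2 arrays, while the B cell receptor chain Cd79b was at -2.25 ± 0.10. Of 5 erythroid and megakaryocyte genes, 1 was higher and 1 was lower, with the same counts adjusted over the list alone. These were the carbonic anhydrase Car2, at 0.97 and 1.03 on arrays 1 and 2, and Pf4, and the list's median of 0.045 (-0.0072 with median centring and -0.42 with spike-in scaling) and mean of -0.41 had opposite signs (camera adjusted p = 0.909). In this group median centring ended the calls, with log2 ratio and adjusted p in brackets, of Cd34 (2.05, 0.459), Gata2 (1.84, 0.163), Cd3g (1.25, 0.21) and Car2 (0.71, 1).

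Adhesion, retinoid and interferon genes also split. Of 23 integrin and adhesion genes, 6 were higher and 6 lower in CD103+ cells, or 8 and 7 adjusted over the list alone. The median of 0.076, or -0.10 with median centring and -0.39 with spike-in scaling, and the mean of -0.12 differed in sign (camera adjusted p = 0.925). L-selectin, encoded by Sell, was at -2.35 ± 0.44, above background in CD103+ cells on 1 of 2 arrays, the integrin chain Itgb5 at -2.15 ± 0.12, the adhesion ligand Icam2 at -1.99 ± 0.26, and Pecam1 at 1.20 ± 0.18. Of 22 genes of retinoid and TGF-beta signalling, 5 were higher and 5 lower, with the same counts adjusted over the list alone, and the median was -0.040, or 0.016 with the scanner's processed signals (camera adjusted p = 0.909). Tgfbi, a matrix protein induced by TGF-beta, was at -3.69 and -2.50 on arrays 1 and 2 and Smad7, an inhibitor of that pathway, at 0.90 and 2.34. The ligand Tgfb3 was at 1.91 ± 0.70, and Ido1, a tryptophan-degrading enzyme, at 1.27 ± 0.076. Of 33 interferon-response genes, 7 were higher and 7 lower, or 8 and 8 adjusted over the list alone, with a median of -0.11, or 0.039 over probes above background in all channels (camera adjusted p = 0.797). Iigp1, an interferon-inducible GTPase, was not well above background in CD103+ cells on either array and was at least 9.89-fold higher in CD103- cells on the mean of the arrays (adjusted p = 3.34e-05). Its log2 ratios against background differed between the arrays, at -2.83 on array 1 and -4.52 on array 2. Ifi27l2a was at -1.93 ± 0.58 and Oas2, above background in CD103+ cells on 1 of 2 arrays, at -1.37 ± 0.15, against 1.20 ± 0.14 for Usp18, which restrains interferon signalling. Among these genes median centring ended the calls, with log2 ratio and adjusted p in brackets, of Itgb5 (-2.42, 0.141), Pecam1 (0.91, 0.52), Tgfbi (-3.27, 0.267), Smad7 (1.31, 0.212), Tgfb3 (1.59, 0.179) and Usp18 (0.88, 0.989).

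Of 16 housekeeping genes, 1 was higher and 0 were lower in CD103+ cells, with the same counts adjusted over the list alone, and the median was 0.048, or -0.22 with median centring and -0.42 with spike-in scaling (camera adjusted p = 0.909). The transferrin receptor Tfrc was at 0.69 ± 0.11 (adjusted p = 0.00857), a call that ended with spike-in scaling (0.22, adjusted p = 0.21) and with median centring (0.37, adjusted p = 1). The adaptor Ywhaz had a ratio of -0.41 ± 0.10 (adjusted p = 0.0895), called with spike-in scaling (-0.87, adjusted p = 0.00172), while a second probe of Ywhaz had the opposite sign at 0.38 ± 0.30 (adjusted p = 0.133). Of 4 sex-linked genes 0 were called by limma over all genes, 0 over the list alone and 0 at an unadjusted p under 0.05, and the Y-linked Ddx3y had a ratio of 0.30 ± 0.18 (list median 0.036, or -0.25 with median centring and -0.43 with spike-in scaling, camera adjusted p = 0.797). Medians on arrays 1 and 2 also had opposite signs for the housekeeping (-0.20 and 0.24), sex-linked (-0.098 and 0.32) and integrin and adhesion lists (-0.12 and 0.12). The same held for the chemokine receptor (-0.23 and 0.22), glycolysis and hypoxia (-0.38 and 0.040), retinoid and TGF-beta (-0.19 and 0.038) and erythroid lists (0.048 and -0.060). In all, 12 of the 28 lists passed camera with its preset correlation. They are not all separate results, since lists share members. Other lists also held 7 of the 24 monocyte and macrophage genes and 6 of the 27 maturation genes. With an estimated correlation 0 passed, also at an unadjusted p under 0.05, and with fry 0 passed after adjustment and 5 before it, while fry's test for change in either direction called 17. Camera with an estimated correlation and fry's directional test rested on 1 residual degree of freedom, so a list that missed there need not be unchanged. Camera with its preset correlation compares genes with genes, so its p-values do not measure the spread between arrays.

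**Figure D3:**
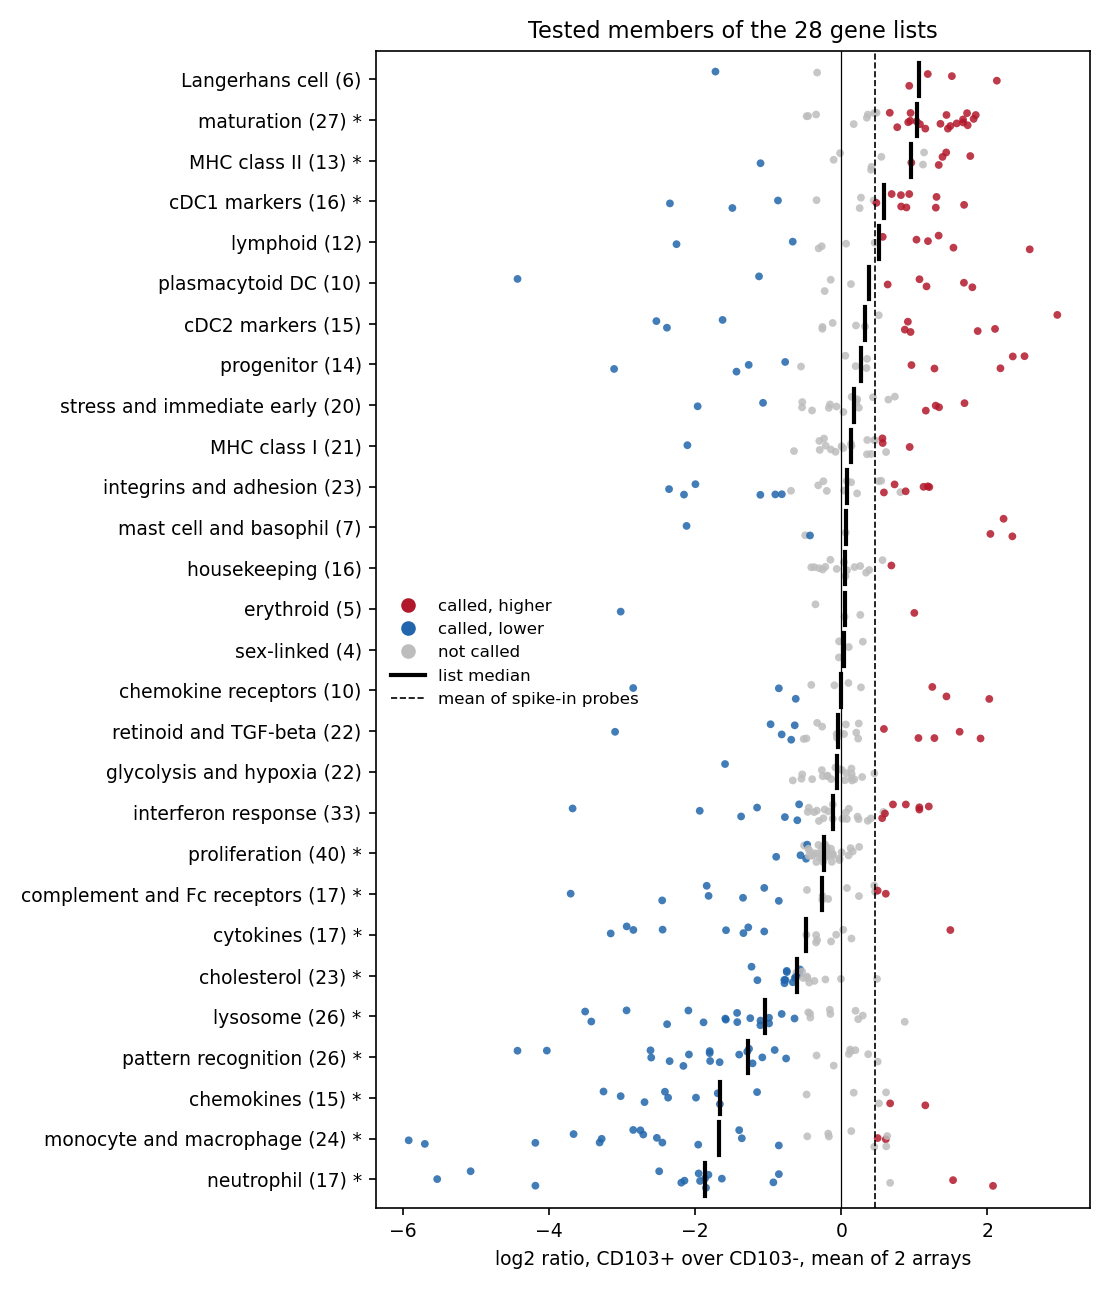
Log2 ratio of CD103+ over CD103- cells (mean of the 2 arrays) for the tested members of the 28 gene lists, 1 point per gene, red for genes called higher, blue for genes called lower and grey for the rest, with list medians as black bars, the number of members in brackets and a star for the 12 lists called by camera. List medians run from -1.86 for neutrophil-associated genes to 1.06 for Langerhans cell genes, and those between 0 and the dashed line at 0.46 lie below 0 with spike-in scaling, and some of them also with median centring.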

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

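Both tests of the spike-in probes were chosen only after the result was seen. The E1A spike-in probes, control RNA outside the comparison of genes, lay higher in the channel of CD103+ cells. Relative to the loess-normalized genes, their mean turned log2 ratio was 0.46 ± 0.093 (SD over 10 probes), or 1.38-fold, with 10 of 10 above 0 and a range from 0.29 to 0.57. The deposited ratios gave 0.498. An effect of the dyes on these probes would turn in opposite directions on the 2 arrays, whereas the scanner's own spike-in fit gave a turned shift of 0.57 on array 1 and 0.42 on array 2, which argues against it. A difference in RNA input or in messenger RNA content per amount of total RNA, with CD103+ cells lower, could give the shift of 0.46, and these cannot be told apart because no input amounts are given. If the shift followed messenger RNA content, the ratios of all genes would fall by it, and 12337 probes would be called lower and 1113 higher in CD103+ cells. These counts take the shift as exact, although it ranged from 0.29 to 0.57 over the probes, an error that all genes would share.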

How the results depend on the processing

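The scaling to spike-in probes was the only setting chosen after the data were seen. Of 1710 tested values for the 123 genes followed, 1621 kept their direction and side of the threshold, 80 lost the call, 9 gained it and 0 reversed. Of 336 tested values for the 28 lists, 307 kept both, 27 lost the call, 2 gained it and 0 reversed. Single arrays, and lists under spike-in scaling, have no test. Median centring in place of loess called 1538 probes, 483 higher and 1055 lower, and lowered the correlation of the arrays to 0.700. It ended the calls of Itgb7 (0.64, adjusted p = 1) and Kit (0.74, adjusted p = 0.792) and of 53 genes in all, as the median SD between arrays went from 0.166 to 0.504. Of the 1538 probes, 1508 were also called, in the same direction, with loess. A 2-fold minimum left 2103 probes, 944 higher and 1159 lower, and by construction ended the calls of Itgb7 (0.88) and Kit (0.96). Spike-in scaling called 13450 probes, 1113 higher and 12337 lower, since it lowers every ratio by 0.46, and left Itgb7 at 0.42 (adjusted p = 0.111). The correlation was 0.859 with the processed signals and with the series values, 0.845 with an offset of 0, 0.806 without a filter on dim probes and 0.831 with a filter on all channels; the cause was not tested. Each array alone gave 2097 to 2476 probes past 2-fold, against 1605 on both, because a single array needs no second. Of 12 lists called by camera, 0 passed with an estimated correlation and 0 with fry, where 2 arrays leave 1 residual degree of freedom. The remaining settings called 4596 to 6645 probes. Signal over background limited the probes tested to 22132 of 41174.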

Other observations

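Gene families defined by their symbols, and lipid genes picked by hand, were examined only after the data were seen, and the test on Itgax was chosen only after the result was seen. Camera values for these families are therefore descriptive. Besides those described below, C-type lectins (camera adjusted p = 0.00506), Fc receptors (0.0161), Cebp genes (0.0161) and Cd300, Lilr and Pir genes (0.0253) were called. Not called were interleukin receptor (0.78), S100 (0.957), Ifit (0.277), Slamf (0.997), Socs (0.78), tubulin (0.764) and serpin genes (0.947). With an estimated correlation no family passed (0.658 or higher). Secreted ribonucleases of the RNase A family, among them the eosinophil-associated ones, were lower in CD103+ cells in 7 of 8 tested members (median -3.06, camera adjusted p = 4.37e-05; 0.658 with an estimated correlation). Ear1 was at -4.27 ± 0.23 and Ear10 at -3.76 ± 0.17, while Rnase6 was at 1.17 ± 0.10. Rnase2b, among the lower ones, was not well above background in CD103+ cells on either array. Whether probes of this family bound each other's transcripts was not examined, so its members may not be separate signals. Both tested formyl peptide receptors, which sense bacterial peptides, were lower, Fpr2 at -4.48 ± 0.024 and Fpr1 at -2.96 ± 0.035. Of 17 genes of lipid uptake, transport and storage, 9 were lower and 2 higher (median -0.80), with the fatty acid carrier Fabp4 at -4.26 ± 0.00050, the nuclear receptor Pparg at -2.56 ± 0.10 and the lipid droplet protein Plin4 at 2.05 ± 0.0047. Of 8 matrix metalloproteinases, 5 were lower, among them Mmp14 at -2.78 ± 0.39, and 2 higher, among them Mmp25 at 1.72 ± 0.37 (median -1.43). Of 18 semaphorin and plexin genes, which guide cell movement, 8 were higher and 0 lower, with a median of 0.29, or -0.18 with spike-in scaling (camera adjusted p = 0.0161; 0.676 with an estimated correlation), and Sema4f at 2.51 ± 0.21 and Sema7a at 1.28 ± 0.13. Of 75 ribosomal protein genes, 7 were called higher and 0 lower, with a median of 0.44, or -0.019 with spike-in scaling. Their camera adjusted p was 4.45e-08, and 0.695 with an estimated correlation. Over all 15223 gene names 1817 were called higher, so 7 of 75 is no excess by count. The count cannot exclude a small common shift, because ratios with wide standard errors were not called. Rps14, for example, had a mean of 0.60 with a standard error of 0.39 (limma adjusted p = 0.316). Members such as Rps14 (-0.17 and 1.37 on arrays 1 and 2) changed sign between arrays, while others such as Rps21 (0.79 and 0.72) did not.

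Neutrophil-associated genes were mostly higher in CD103- cells, although both sorts took CD11c-positive cells and Ly6G-positive cells were removed before culture. Neutrophils inside the CD103- gate could account for it, and 5 of 7 transcripts abundant in neutrophils were at least 2-fold higher there on both arrays, among them Ltf at -2.19 ± 0.61 and Ngp at -2.14 ± 0.55, while Cxcr2 was at -0.85 ± 0.41 and Retnlg, not well above background in CD103+ cells, was at least 1.42-fold higher in CD103- cells. All 7 belong to the neutrophil list, so their ratios are part of the pattern itself and are not independent support. The mean log2 levels in CD103- and CD103+ cells, which cannot be ranked across probes, were 16.5 and 12.3 for S100a9 and 12.6 and 10.4 for Ltf, and Stfa2 went the other way at 2.08 ± 0.26. Macrophages or monocytes inside the gate could account for it too. The ratio of Itgax of -0.096, or 0.29 at a second probe, leaves them open, since such cells can carry CD11c. These sources cannot be told apart from expression by the CD103- dendritic cells themselves, because each population was measured as a bulk, and 1 of the 17 list genes is also held by another list.

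Some genes best known from T and NK cells, Cd7, Il2ra and Txk among them, were higher in CD103+ cells, although the lymphoid list was not called and CD3-positive and NK cells were removed before culture. NK cells inside the CD103+ gate would bring their abundant transcripts, but 0 of 6 were well above background there and at least 2-fold higher on both arrays, which argues against them. T cells inside the CD103+ gate would bring all CD3 chains, of which 1 of 3 met that mark, with Cd3g at 1.54 ± 0.0045, Cd3d at 1.03 ± 0.17 and Cd3e at 0.067 ± 0.53. The mean log2 levels in CD103+ and CD103- cells, which cannot be ranked across probes, were 10.9 and 9.38 for Cd3g and 8.64 and 8.58 for Cd3e, and 0 of the 12 lymphoid list genes are held by another list. By the rule set beforehand, 1 of 3 argues against T cells as the source of these genes. Cd3d was within 1 SD of the 2-fold mark on array 1, a margin set after the values were seen. Even with that margin not all chains met the mark, since Cd3e was at -0.31 and 0.44 on arrays 1 and 2. A few T cells that add to Cd3g and Cd3d cannot be told apart from expression by CD103+ dendritic cells, because each population was measured as a bulk.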
